A study of Arabidopsis thaliana with 12 samples.

How the data were processed

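Whole Arabidopsis thaliana seedlings of 2 genotypes were measured on single-colour Agilent arrays with 45220 spots, 43803 of them for non-control probes. Per the labels' protocols, Col-0 wild type and a line called hb52-KO grew for 5 days in nitrogen-free Murashige and Skoog liquid medium supplied with 10 mM ammonium, and 10 mM KNO3 or 10 mM KCl, the control salt, was then given for 1 day. RNA was taken with the Maxwell RSC RNA kit and 0.2 µg of it was amplified and labelled with Cy3, per the labels' protocols. There were 4 groups of 3 arrays, 12 arrays in all, and the labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

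Each deposited scanner file holds intensity values of Agilent Feature Extraction, version 9.1 per the submitters' processing notes and 9.1.3.1 per the file headers. Per the file headers, the deposited processed intensity had its background removed by a fitted spatial surface and was detrended within the array, and no scaling between arrays was made. The deposited value table of the series matched the median pixel intensity of each spot, without background subtraction and on a linear scale, except for the HB52 spot on array 2 of hb52-KO with KNO3, and was not centred. Its column medians on arrays 1 to 3 were 294.5, 179 and 166.2 for wild type with KCl, 304, 243 and 213 for wild type with KNO3, 160, 123 and 163 for hb52-KO with KCl, and 249, 117 and 206.5 for hb52-KO with KNO3. On 9 of the 12 arrays the deposited numbers were rounded to 3 digits.

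The value analysed was log2 of the processed intensity minus the array's 75th percentile of it over non-control probes, called the normalized log2 signal. Spots marked as outliers by the scanner software were left out, and spots of a probe were averaged. A probe was kept if it was well above background on all 3 arrays of at least 1 group (33048 probes) and had at least 2 unmarked values in every group (33001 probes). For each gene the probe with the highest mean over all arrays was used, which left 21346 genes. Of 43603 non-control probes, 36163 were named through their transcript accession, 573 through a locus tag and 442 through a symbol in the RefSeq gene table of assembly TAIR10.1, and 6425 had no gene there and are not named. The table was used for names and gene order only. Of 6705 genes with several probes, 21 had probes called in opposite directions for the nitrate response of hb52-KO, 9 for the genotype difference under KCl, and none for the other comparisons.

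A mean per group was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with defaults, no covariates; files were read with the R package data.table, version 1.17.8), and 5 contrasts were tested. Throughout, an adjusted p is limma's with Benjamini-Hochberg adjustment over genes, a gene was called at adjusted p under 0.05, and ± after a log2 difference is the standard error of the fit from 3 arrays per group. Where a gene was not well above background on any array of the dimmer group, the fold is a bound, written "at least". It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal.

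Before the data were examined, 31 gene lists with 411 members were fixed, and 26 members whose gene ID and symbol the tables did not pair were left out. The 30 lists with at least 4 tested members were tested with limma's camera (preset correlation 0.01), with adjustment over the lists of a contrast, and again with a correlation estimated from the data. The list of CC-type glutaredoxins had too few members on the arrays and was not tested. For the set tests 173 missing values were filled with the group mean. Genes named for the 5 contrasts were drawn by a rule fixed at the same time: in every contrast HB52, AT1G27050 (HB54) and 4 FtsH genes, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, and up to 4 members, in order of adjusted p, of the lists with the 10 smallest camera p-values and, for the nitrate contrasts, of the nitrate lists. A subset of 23 nitrate-inducible genes was drawn from these lists after their values had been seen, and so were the members of other lists named among the other observations.

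The 3 slides of 4 arrays each held 1 array of every group, and slide, scan and replicate number coincided. The position on the slide was the same for all 3 arrays of a group. Alternatives were quantile or median normalization, normexp background correction with an offset of 50, no or a stricter filter on dim probes, other ways of joining probes, the replicate or slide as a block, separate fits, other variance models, array weights, the deposited value table, a fold of at least 2, other set tests and leaving out each array. The 2 arrays that stood apart from their group were also left out together, an alternative added after seeing the data.

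The scripts were tested on simulated arrays with the real means and spreads, in which 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold among 21346. For the nitrate response in wild type the fit recovered 7.46%, 47.8% and 84.8% of them, for the nitrate response in hb52-KO 10.4%, 44.8% and 72.7%, for the genotype difference under KCl 11.9%, 37.3% and 75.8%, for that under KNO3 17.9%, 32.8% and 78.8%, and for the interaction 0%, 14.9% and 63.6%. In the data 11145 genes were called for nitrate in hb52-KO and 7711 between genotypes under KCl, far more than were changed here. The adjustment over genes depends on how many differ, so the recovered shares do not describe those contrasts. False calls made up 8.82%, 11.5%, 6.74%, 8.51% and 5.45% of the calls in that order, above the threshold of 0.05 in each. Each share came from a single draw, with 9, 11, 6, 8 and 3 false calls. Whether the fit exceeds its threshold beyond the spread between draws was not tested. A list shifted in the simulated wild-type nitrate response was called and 0 other lists were. Genes were drawn independently there, so this run could not show false list calls that come from correlation between genes. The number of arrays, 3 per group, limits the precision.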

Results

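The study asked how nitrate changes gene expression in Arabidopsis seedlings and whether the change differs in hb52-KO, a line named as a knockout of HB52 (AT5G53980), which encodes a homeodomain-leucine zipper transcription factor. Seedlings grown on ammonium as their nitrogen source received 10 mM KNO3 or 10 mM KCl for 1 day, and 3 arrays were hybridised for each of the 4 combinations of genotype and salt. Between 69.9% and 82.45% of the spots on an array were well above background, and no spot was saturated. The 75th percentile of the processed signal ran from 419 on array 2 of hb52-KO with KNO3 to 1680 on array 1 of wild type with KNO3. Groups are named here by their labels throughout.

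By its processed signal, HB52 stood at a similar level on all 12 arrays. Its normalized log2 signal was -1.47 ± 0.47 (SD, n = 3) in wild type with KCl, -2.11 ± 0.29 in wild type with KNO3, -1.93 ± 0.40 in hb52-KO with KCl and -2.10 ± 0.25 in hb52-KO with KNO3. The arrays labelled hb52-KO differed from wild type by -0.46 ± 0.28 under KCl (adjusted p = 0.2) and by 0.01 ± 0.28 under KNO3 (adjusted p = 0.99). Within slides 1 to 3 the difference under KCl was 0.02, -1.11 and -0.29. The nitrate difference was -0.64 ± 0.28 in wild type (adjusted p = 0.3) and -0.17 ± 0.28 in hb52-KO (adjusted p = 0.635). The processed signal therefore did not check the genotype label; where the gene is disrupted relative to the probe is not given in the sources used here, and a probe outside the disrupted part checks nothing. A second HB52 probe was not well above background on any array. In the deposited value table, which holds the median pixel signal, the HB52 spot read 2588, 2491.5 and 2245 on the wild-type KCl arrays against 102, 170 and 230 on the hb52-KO KCl arrays, and 7491.5, 5270 and 6281 on the wild-type KNO3 arrays against 404, 430 and 382 on the hb52-KO KNO3 arrays, and the difference was -3.48 under KCl (adjusted p = 0.0096) and -3.34 under KNO3 (adjusted p = 0.0674). On 9 arrays the median pixel signal in the scanner output lay 1.59 to 102.7 pixel standard deviations from the mean pixel signal of the same spot. On array 2 of hb52-KO with KNO3 that median was 230, where the value table held 430. A median cannot lie farther from the mean of the same pixels than their standard deviation. These medians and means therefore cannot describe the same pixels, and the differences from the value table do not check the genotype label. Which of them is wrong was not tested, so the level of HB52 on these 9 arrays stays open.

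**Figure D1:**
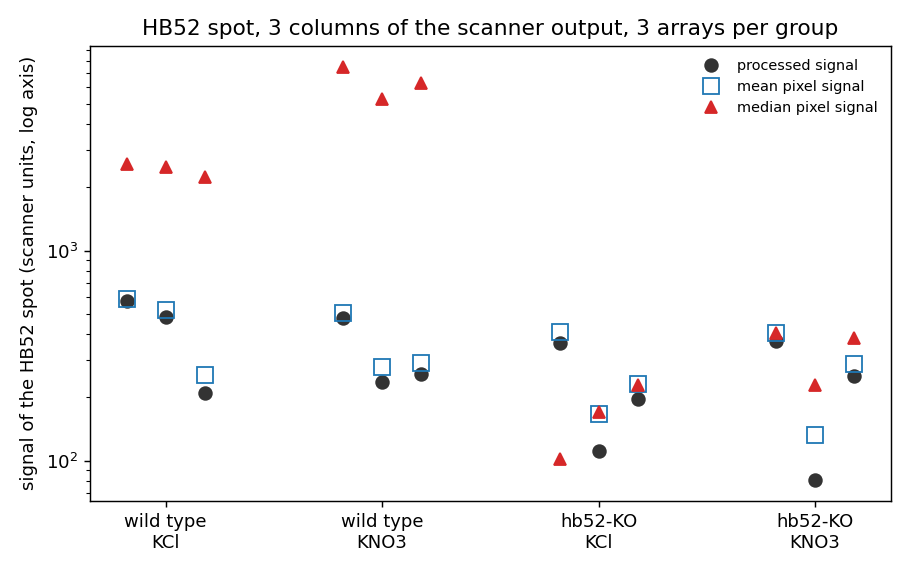
Signal of the HB52 spot on each of the 12 arrays in 3 columns of the scanner output (log axis, scanner units), with 3 arrays per group. The processed and mean pixel signals overlap between genotypes, between 81.1 and 589 in all, and the median pixel signal of wild type lies at 2245 to 7491.5.

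Arrays of a group correlated with each other across genes at r between 0.956 and 0.9902. The first principal component held 61.1% of the variance over 21206 genes and placed the hb52-KO KCl arrays at 142, 82.6 and 85. Array 2 of wild type with KCl lay at 56.51, nearer to these than to the other 2 arrays of its own group at -53.42 and -27.19. The remaining arrays lay between -12.85 and -85.09. Array 2 of hb52-KO with KCl had the highest share of spots above background, 82.45%, and a bright-corner control signal of 1152, against 233.5 to 397 on the other arrays.

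**Figure D2:**
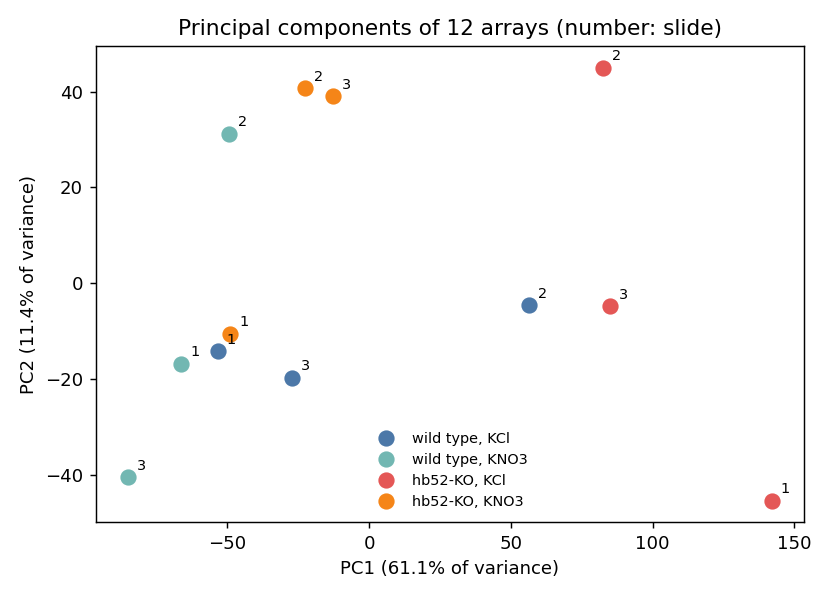
First and second principal components of the 12 arrays, holding 61.1% and 11.4% of the variance, with points coloured by group and numbered by slide. The 3 arrays of hb52-KO with KCl and array 2 of wild type with KCl lie to the right at 56.51 to 142, and the other 8 arrays lie at -12.85 or lower.

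The first comparison asked which genes nitrate changed in wild type. Several genes of nitrate assimilation and signalling had lower signals on the KNO3-labelled arrays. NIR1 (AT2G15620), which encodes nitrite reductase, was 5.22-fold lower (log2 difference -2.38 ± 0.27, adjusted p = 0.0212), and NIA2 (AT1G37130), a nitrate reductase gene, was 3.66-fold lower (-1.87 ± 0.20, adjusted p = 0.0162). The regulators BT2 (AT3G48360, -3.19 ± 0.28, 9.15-fold, adjusted p = 0.00436) and LBD37 (AT5G67420, -1.14 ± 0.14, 2.21-fold, adjusted p = 0.034), both known as nitrate-induced, were lower as well. The other falls were AT2G21210, at least 28.4-fold lower and not well above background on any KNO3 array (adjusted p = 0.034), AT1G49500 (-3.22 ± 0.26, adjusted p = 0.00363) and the beta-glucosidase gene BGLU25 (AT3G03640, -3.11 ± 0.35, adjusted p = 0.0212). The 2 rises were AT1G22160 (1.51 ± 0.19, adjusted p = 0.033) and AT2G36970 (1.16 ± 0.15, adjusted p = 0.0366). These 9 genes were all that limma called, 2 higher and 7 lower, and each had the same sign on all 3 slides. At an unadjusted p under 0.05 there were 3494 genes, and 18.6% of genes had groups that did not overlap, against 10% by chance. The count was 5 with the slide as a block, of which BT2, AT1G49500, BGLU25 and NIA2 were among the 9 while NIR1 (adjusted p = 0.075) and LBD37 (adjusted p = 0.127) were not, and 0 when the 6 wild-type arrays were fitted alone. It was 14 without KCl array 1, 2 without KCl array 3, without KNO3 array 1 or without KNO3 array 3, 3 without hb52-KO KNO3 array 1, and 2 without hb52-KO KNO3 array 2. Of 27 alternatives NIR1 was called in 16 and LBD37 in 8, and none of the 9 genes was called in all. Of the nitrate assimilation and signalling genes above, NIR1 (adjusted p = 0.0636) and LBD37 (adjusted p = 0.0782) were not called without KCl array 2. NIA2 (adjusted p = 0.0442) and BT2 (adjusted p = 0.00165) were.

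Of the gene lists fixed in advance, camera called 8 of 30 in wild type, 2 upward and 6 downward, and no list with a correlation estimated from the data; it called 4 without KCl array 1 and 5 without KNO3 array 3. Nitrate reduction and siroheme genes were lower on the KNO3-labelled arrays, with 2 of 6 called, and 1 higher and 5 lower adjusted over the list alone (median log2 difference -1.39, and -1.70, -0.61 and -1.47 on slides 1 to 3). Its camera adjusted p was 0.000145, 0.00101 with the slide as a block, and the adjusted p = 0.207 with an estimated correlation. In the nitrate-linked regulators 2 of 27 were called, both lower, and 5 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.143). BT1 had a difference of -2.13 ± 0.33 (adjusted p = 0.0823) and CIPK3 of -1.02 ± 0.17 (adjusted p = 0.127). None of 17 nitrate transport genes was called, 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.356). NRT2.5, a high-affinity nitrate transporter known from nitrogen-starved plants, was 6.08-fold higher without passing (adjusted p = 0.127), and the nitrate transceptor gene NRT1.1 had 0.83 ± 0.17 (adjusted p = 0.165). Without KCl array 2, NRT2.5 (adjusted p = 0.0126), BT1 (adjusted p = 0.0336) and CIPK3 (adjusted p = 0.0131) passed.

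No member of the other called lists passed by itself in wild type. Phosphate starvation genes had a median of -0.77 over 19 (1 lower adjusted over the list alone, camera adjusted p = 0.00115), with PHO1;H1 at -1.55 ± 0.28 (adjusted p = 0.14). Heat shock genes had a median of -1.31 over 5 (5 lower adjusted over the list alone, camera adjusted p = 0.00176), with HSFA2 at -1.31 ± 0.45, and the list's median was -1.28, -0.32 and -2.52 on slides 1 to 3. Medians were also below 0 for sulfate assimilation (-0.61 over 15, camera adjusted p = 0.0227), reductant supply for nitrite reduction (-0.32 over 6, 0.0328) and dark-induced and senescence genes (-0.23 over 11, 0.0339), with 0 called adjusted over the list alone. Cytokinin genes had a median of 0.48 over 21 (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0429), led by the cytokinin oxidase gene CKX5 and the response regulators ARR16 (1.26 ± 0.38) and ARR7 (1.14 ± 0.35). FtsH proteases and photoprotection genes had a median of 0.33 over 9 (0 adjusted over the list alone, camera adjusted p = 0.0429). With an estimated correlation the adjusted p was 0.711 for all of these but the sulfate list, where it was 0.783. The senescence list had a median of 0.09, -0.52 and -0.30 on slides 1 to 3, and the other called lists kept their sign on all 3. The slide block took the cytokinin list to an adjusted p of 0.0521, and quantile normalization took the senescence list to 0.081 and normexp the FtsH list to 0.238. Calls ended without KCl array 1 for the FtsH, cytokinin, reductant and sulfate lists, without KCl array 2 for FtsH (adjusted p = 0.299) and sulfate (adjusted p = 0.288), and without KCl array 3 for cytokinin and senescence. They also ended without KNO3 array 2 for cytokinin and senescence, without KNO3 array 3 for FtsH, reductant and sulfate, without hb52-KO KCl array 2 for FtsH and without hb52-KO KCl array 3 for cytokinin. AT1G27050 (0.55 ± 0.24), FTSH1 (0.48 ± 0.20), VAR2 (0.19 ± 0.17), VAR1 (0.14 ± 0.14) and FTSH8 (0.25 ± 0.16) did not pass. Chlorophyll synthesis (median 0.31, camera adjusted p = 0.136) and jasmonate genes (median -0.54, camera adjusted p = 0.139) were not called, nor were the 18 lists not described.

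**Figure D3:**
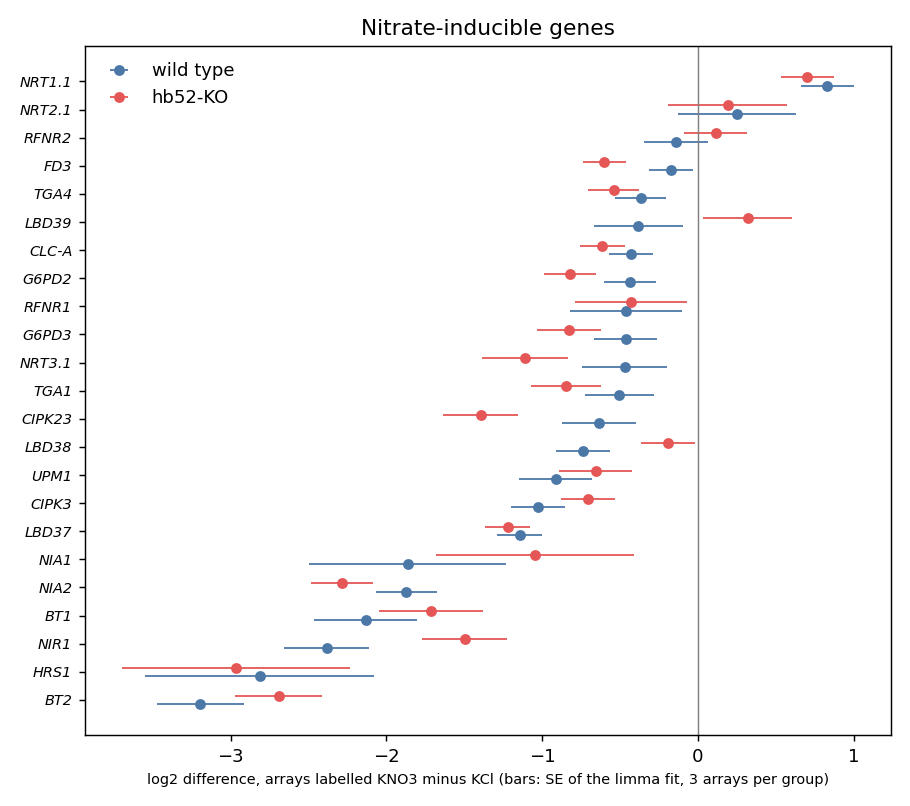
Log2 difference of 23 nitrate-inducible genes between arrays labelled KNO3 and KCl, in wild type and in hb52-KO, with standard errors of the limma fit from 3 arrays per group. NRT1.1 and NRT2.1 lie above 0 in both genotypes, and 19 of the 23 genes lie below 0 in both, with BT2 at -3.19 and -2.69.

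In hb52-KO much of the measured genome differed between the salts. The largest rises on the KNO3-labelled arrays were AT2G33850 (4.56 ± 1.36, adjusted p = 0.019), AT5G18030 (4.54 ± 1.08, adjusted p = 0.00796), MLP34 (4.50 ± 0.83, adjusted p = 0.00378), AT4G22505 (4.34 ± 0.95), SAUR23 (4.25 ± 0.92), a gene of the auxin-induced SAUR family, and AT1G29450 (4.14 ± 1.05). In the KCl group AT2G33850 was well above background on 2 arrays and AT5G18030, SAUR23 and AT1G29450 on 1. On array 1 of that group these genes read -8.262 to -8.896, below -6.771, the lowest signal there among probes well above background. Their differences, and their place against MLP34 and AT4G22505, are therefore not exact. The largest falls were AT1G18830 (-4.71 ± 0.61, 26.1-fold, adjusted p = 0.00217), BIP3 (-4.56 ± 0.54, adjusted p = 0.00209), a chaperone gene of the endoplasmic reticulum, and the cytochrome P450 gene CYP71B22 (-4.15 ± 0.60). AT1G80470 was at least 7.41-fold lower and the beta-amylase gene BAM5 at least 8.86-fold lower (adjusted p = 0.00273 and 0.0187), neither being well above background on any KNO3 array, and AT1G61080 was at -3.95 ± 0.74. In all, limma called 11145 of 21346 genes, 5959 higher and 5186 lower, and 5169 of them changed at least 2-fold. The groups did not overlap for 67.4% of genes. The count was 11129 with the slide as a block, of which 10559 were among the 11145, 12326 without array 2 of wild type with KCl and 7268 with normexp background correction. Scaling by the median in place of the 75th percentile moved the median of all genes by -0.32 and the share of higher calls from 53.5% to 33.7%.

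Photosystem genes were called as a list on the KNO3-labelled arrays of hb52-KO, as were 5 others, and each of the 6 had adjusted p = 0.71 with an estimated correlation. Of 31 photosystem and Calvin cycle genes 29 rose and 0 fell, 30 adjusted over the list alone (median 1.22, and 1.49, 1.51 and 0.58 on slides 1 to 3; camera adjusted p = 3.53e-09). The antenna gene LHCB5 rose 2.65-fold (1.41 ± 0.22), the photosystem I gene PSAK 2.45-fold (1.29 ± 0.21) and LHCA3 2.35-fold (1.23 ± 0.20). Of 12 chlorophyll synthesis genes 10 rose, also adjusted over the list alone (median 1.28, camera adjusted p = 0.00132), among them GUN5 (1.39 ± 0.21), which encodes a subunit of magnesium chelatase, CRD1 (1.46 ± 0.23) and GUN4 (1.45 ± 0.24). In the auxin list 14 of 21 rose and 2 fell, 15 and 2 adjusted over the list alone (median 1.62, camera adjusted p = 0.00041). The auxin-response repressors IAA1 (2.63 ± 0.25, 6.19-fold, adjusted p = 0.00129) and IAA2 (1.62 ± 0.15) and the carriers LAX3 (1.91 ± 0.26) and PIN4 (1.52 ± 0.23) rose. Of 8 cell division genes 7 rose, also adjusted over the list alone (camera adjusted p = 0.0394), with a median of 3.99, 1.69 and 0.62 on slides 1 to 3. CYCD3;1 rose 4.36-fold (2.13 ± 0.38) and the cytokinesis syntaxin gene SYP111 5.66-fold.

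In the same comparison phosphate starvation and senescence lists went down. Of 19 phosphate starvation genes 12 fell and 0 rose, also adjusted over the list alone (median -1.22, camera adjusted p = 0.000257), with the phosphate transporter genes PHT1;2 at -2.37 ± 0.38 and PHT1;3 at -1.39 ± 0.24 and the regulator SPX2 at -1.13 ± 0.22. Of 11 dark-induced and senescence genes 4 fell, also adjusted over the list alone (median -0.45, camera adjusted p = 0.035), including SAG13 (-2.44 ± 0.41) and DIN2 (-1.65 ± 0.33). For both lists the adjusted p was 0.71 with an estimated correlation, and with the slide as a block the cell division list had an adjusted p of 0.0571. Without array 2 or array 3 of wild type with KCl the cell division list had adjusted p = 0.077 and 0.0529. The senescence call ended with quantile normalization (adjusted p = 0.0533) and without array 1 of hb52-KO with KCl (adjusted p = 0.0515), and 10 lists were called without wild-type KNO3 array 2, wild-type KNO3 array 3, hb52-KO KCl array 2 or hb52-KO KNO3 array 3.

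Nitrate assimilation genes were again lower on the KNO3-labelled arrays of hb52-KO. NIA2 fell 4.87-fold (-2.29 ± 0.20, adjusted p = 0.00129), NIR1 2.82-fold (-1.50 ± 0.27), B73, a gene of the same list, 2.27-fold (-1.18 ± 0.18) and BT2 6.46-fold (-2.69 ± 0.28), while the molybdenum cofactor gene CNX3 rose 1.34-fold (0.42 ± 0.12). In the nitrate reduction and siroheme list 4 of 6 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0559). Of 27 nitrate-linked regulators 6 rose and 12 fell, also adjusted over the list alone, with CRF4 at 2.01 ± 0.29 and the kinase gene CIPK23 at -1.40 ± 0.24 (camera adjusted p = 0.275). Of 17 nitrate transport genes 6 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.653), with AT1G52190 at 2.63 ± 0.40, NRT2.5 at 2.28 ± 0.44 and NRT1.9 at 1.15 ± 0.19. Of 6 reductant supply genes 4 fell, also adjusted over the list alone (camera adjusted p = 0.0689), G6PD2 by 0.82 ± 0.17 and FD3 by 0.60 ± 0.14. The FtsH and photoprotection list (5 of 9 higher, camera adjusted p = 0.0559), sulfate assimilation (5 of 15 lower, 0.0559) and hypoxia genes (3 of 8 lower, 0.0689) had the same counts adjusted over the list alone and were not called as lists. AT1G27050 (0.97 ± 0.24, adjusted p = 0.00873) and VAR1 (0.61 ± 0.14, adjusted p = 0.00694) rose, and FTSH1 (0.46 ± 0.20), VAR2 (0.19 ± 0.17) and FTSH8 (0.03 ± 0.16) did not pass. Without array 2 of wild type with KCl FTSH1 passed (adjusted p = 0.0431), and with median scaling VAR1 did not. The 17 lists not described held no call by camera.

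The nitrate responses of the 2 genotypes, which share no array, correlated across genes at r = 0.751, and genes are not independent replicates. All 9 genes called in wild type, BT2, NIA2, NIR1 and LBD37 among them, had the same sign and a call in hb52-KO, where independent lists would share 2.26. Over all genes 83.2% had the same sign. Of 23 genes known as nitrate-inducible, chosen after their values were seen, 19 were lower on the KNO3-labelled arrays in both genotypes, against 36.9% of all genes. Called lower were 4 of the 23 in wild type and 16 in hb52-KO, where NRT1.1 was called higher. NRT2.1 stood at 0.25 ± 0.38 in wild type (adjusted p = 0.723) and at 0.19 ± 0.38 in hb52-KO (adjusted p = 0.69), and at -0.11 in wild type without KCl array 2. The correlation within slides 1 to 3 was 0.159, 0.619 and 0.533, and it was 0.495 without array 2 of wild type with KCl.

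Under KCl the arrays labelled hb52-KO differed from wild type most in a few genes with a gap far beyond the replicate spread. SR30 (AT1G09140), a splicing factor gene, was 434-fold lower (-8.76 ± 0.23, adjusted p = 4.71e-08), and QQS (AT3G30720), known to affect starch content, was 79.5-fold lower (-6.31 ± 0.17, adjusted p = 4.71e-08). VAR2 (AT2G30950), which encodes a subunit of the FtsH protease of thylakoids, was 23.8-fold lower (-4.58 ± 0.17, adjusted p = 8.2e-07). AT2G21210 (-3.52 ± 0.63), the myrosinase gene TGG2 (-3.50 ± 0.95) and the anthocyanin gene LDOX (-3.38 ± 0.96) followed. On the hb52-KO arrays these were well above background on 2, 2 and 1 of 3 arrays, so their differences and order are not exact. AT1G05540 was 226-fold higher (7.82 ± 0.59, adjusted p = 0.000335), MRD1 (AT1G53480) 11.8-fold (3.56 ± 0.32) and the meiotic crossover gene HEI10 (AT1G53490) 6.53-fold (2.71 ± 0.13). AT2G14690 (3.37 ± 0.73) and TSM1 (2.73 ± 0.86) were well above background on 1 wild-type array, so their differences are not exact. TSM1 read -9.698 and -8.207 on wild-type arrays 1 and 3. The lowest signals there among probes well above background were -7.759 and -6.701. AT1G11040 was at least 3.39-fold higher (adjusted p = 0.0305). In all 7711 genes were called, 3445 higher and 4266 lower, 3214 of them at least 2-fold, and groups did not overlap for 43.3% of genes. The count was 7178 with the slide as a block, of which 6570 were among the 7711, 8 when only the 6 KCl arrays were fitted, 2561 with normexp, 4243 with the deposited value table, and with median scaling the share of higher calls moved from 44.7% to 65.2%. With quantile normalization SR30 stood at -2.18. The probe of each gene was chosen anew in that setting, so this value may come from another SR30 probe than the 434-fold drop. That drop is the change of the probe used in the reported fit, and it does not settle the fold of the gene as a whole. Called in all 27 alternatives were SR30, QQS, VAR2, AT1G05540, MRD1, HEI10 and IAA1. The count was 950 without wild-type array 1, 12150 without wild-type array 2, 1406 without wild-type array 3, 1399 without hb52-KO array 1 and 4969 without hb52-KO array 2.

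Lists of photosynthesis, pigment and auxin genes were called lower on the hb52-KO arrays under KCl, and for each of the 8 lists called the adjusted p was 0.728 with an estimated correlation. Of 31 photosystem and Calvin cycle genes 27 were called lower, also adjusted over the list alone (median -1.13, and -1.29, -0.91 and -0.98 on slides 1 to 3; camera adjusted p = 8.1e-11), with LHCA2 at -1.37 ± 0.23, LHCB5 at -1.33 ± 0.22 and PSAH2 at -1.45 ± 0.25. Of 12 chlorophyll synthesis genes 8 were lower, also adjusted over the list alone (camera adjusted p = 0.000451), with GUN4 at -1.26 ± 0.24 and CHLI1 at -1.42 ± 0.31. In the auxin list 13 of 21 were lower and 2 higher, 14 and 2 adjusted over the list alone (median -1.47, camera adjusted p = 0.000451), with IAA1 at -2.42 ± 0.25 (5.35-fold), PIN7 at -1.95 ± 0.28 and LAX3 at -1.84 ± 0.26. Of 18 anthocyanin and flavonoid genes 12 were lower, 1 higher and 15 lower adjusted over the list alone (camera adjusted p = 0.00101), with a median of -3.84, -1.01 and -0.56 on slides 1 to 3. The pigment regulators MYB90 (3.99-fold) and TT8 (-1.59 ± 0.41) were among them. Of 9 FtsH and photoprotection genes 5 were lower, 6 adjusted over the list alone (camera adjusted p = 0.00318), VAR2 and the energy-quenching gene NPQ4 (-1.42 ± 0.24) leading and VAR1 at -0.55 ± 0.14. Of 5 guard cell and stomatal lineage markers 4 were lower, also adjusted over the list alone (camera adjusted p = 0.0106), MYB60 by -1.51 ± 0.17 and SPCH, the initiator of the stomatal lineage, by -2.31 ± 0.52.

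Phosphate starvation and senescence lists were called higher under KCl on the hb52-KO arrays. Of 19 phosphate starvation genes 13 were higher and 1 lower, 14 and 1 adjusted over the list alone (median 1.07, and 1.68, 0.49 and 0.97 on slides 1 to 3; camera adjusted p = 0.000451), with PHT1;2 at 1.55 ± 0.38 and SPX2 at 0.91 ± 0.22. Of 11 dark-induced and senescence genes 5 were higher, 8 adjusted over the list alone (camera adjusted p = 0.00255), with SAG13 at 2.06 ± 0.41 and DIN2 at 1.67 ± 0.33. For both the adjusted p was 0.728 with an estimated correlation, and all 8 called lists were called with the slide as a block. Cell division (4 of 8 lower, 1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0613) and iron deficiency genes (8 of 16 lower and 1 higher, also adjusted over the list alone, 0.0811), NAS4 at -2.16 ± 0.38 among them, were not called as lists. AT1G27050 stood at -0.69 ± 0.24 (adjusted p = 0.045), a call held in 8 of 27 alternatives and lost with the slide as a block and without any 1 of 11 arrays, and FTSH1 (-0.27 ± 0.20) and FTSH8 (-0.02 ± 0.16) did not pass. Root tissue markers were not called (1 of 8 higher and 1 lower, camera adjusted p = 0.55), nor were the other 19 lists. Array 2 of wild type with KCl, which lay near the hb52-KO KCl arrays on the first principal component, is the wild-type array of slide 2.

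Under KNO3 the arrays labelled hb52-KO differed from wild type in 8 called genes. SR30 was 122-fold lower (-6.93 ± 0.23, adjusted p = 3.56e-07), QQS 62.6-fold lower (-5.97 ± 0.17, adjusted p = 1.66e-07), VAR2 23.8-fold lower (-4.57 ± 0.17, adjusted p = 8.25e-07) and MAF5 (AT5G65080), a relative of the flowering repressor FLC, 4.63-fold lower (-2.21 ± 0.15, adjusted p = 0.0002). AT1G05540 was 57.3-fold higher (5.84 ± 0.59, adjusted p = 0.00455), MRD1 12.5-fold (3.64 ± 0.32, adjusted p = 0.0015), AT5G03090 7.45-fold (2.90 ± 0.36, adjusted p = 0.0272) and HEI10 2.98-fold (1.58 ± 0.13, adjusted p = 0.000961). The normalized log2 signal of VAR2 was 5.10 ± 0.20 (SD, n = 3) in wild type and 0.53 ± 0.14 in hb52-KO. Other FtsH genes did not pass, with FTSH1 at -0.29 ± 0.20, VAR1 at -0.08 ± 0.14 and FTSH8 at -0.24 ± 0.16, nor did AT1G27050 at -0.28 ± 0.24. At an unadjusted p under 0.05 there were 1880 genes, and 24.5% of genes had groups that did not overlap. With the slide as a block 7 genes were called, all among the 8, AT5G03090 being lost. Array weights gave 10531 calls, and normexp ended the calls of AT5G03090 and HEI10. AT1G05540 stood at 6.73 without wild-type KNO3 array 3 and at 4.34 with normexp, and was not called when only the 6 KNO3 arrays were fitted (adjusted p = 0.195). SR30 stood at -2.36 with quantile normalization, where the probe was chosen anew and may be another than that of the 122-fold drop. The 122-fold drop is thus the change of the probe used, and does not settle the fold of the gene. AT5G03090 was called in 12 of 27 alternatives.

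**Figure D4:**
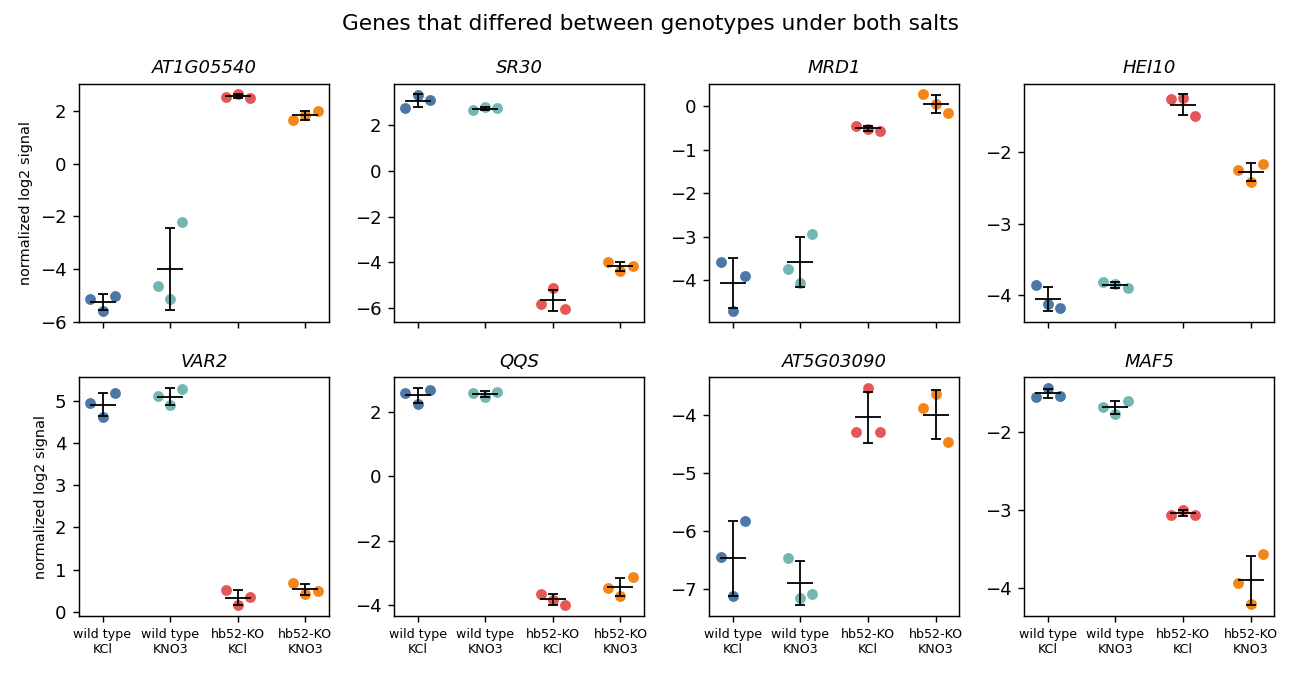
Normalized log2 signal of the 8 genes called between genotypes under KNO3, for each array, with the mean and SD of 3 arrays per group. SR30, QQS, VAR2 and MAF5 are lower on the arrays labelled hb52-KO under both salts, and AT1G05540, MRD1, HEI10 and AT5G03090 are higher.

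Camera called 10 of 30 lists between genotypes under KNO3, 4 upward and 6 downward, with VAR2 as the single called member, and no list with an estimated correlation, where adjusted p-values of these lists lay between 0.434 and 0.826. It called 6 without wild-type KCl array 2 or hb52-KO KNO3 array 1 and 16 without wild-type KNO3 array 3. Higher medians were found for dark-induced and senescence genes (0.52 over 11, camera adjusted p = 0.000319), heat shock genes (1.39 over 5, 0.000319), salicylate and camalexin genes (0.62 over 9, 0.0011) and phosphate starvation genes (0.16 over 19, 0.0272). DIN2 stood at 0.97 ± 0.33, HSP21 at 1.98 ± 0.55, the defence regulator WRKY70 at 1.04 ± 0.21 and IPS1 at 1.97 ± 0.77, with adjusted p between 0.443 and 0.565. Lower medians were found for FtsH and photoprotection (-0.37 over 9, 0.000319), iron deficiency (-0.52 over 16, 0.000646), anthocyanin (-0.65 over 18, 0.0217), starch and organic acid metabolism (-0.21 over 10, 0.0454), acid and STOP1-linked (-0.42 over 7, 0.0454) and guard cell genes (-0.39 over 5, 0.0454). MYB10 stood at -1.36 ± 0.49, the anthocyanin regulator PAP1 at -1.83 ± 0.68, the potassium transporter HAK5 at -1.99 ± 0.68 and MYB60 at -0.39 ± 0.17, each with adjusted p = 0.565. Adjusted over the list alone, 1 gene was called higher in the heat shock list and 1 in the salicylate list, 1 lower (VAR2) in the FtsH list, and 0 in the other 7. The heat shock median was 0.78, 0.20 and 3.12 on slides 1 to 3 and the phosphate median -0.10, 0.02 and 0.90, and the other 8 lists kept their sign on all 3. The phosphate call ended without wild-type KNO3 array 3 (adjusted p = 0.308) or hb52-KO KNO3 array 3 (adjusted p = 0.537). The anthocyanin, starch, acid and guard cell calls each ended without wild-type KCl array 2 (adjusted p = 0.0565, 0.0819, 0.0715 and 0.0672), without wild-type KNO3 array 2 (adjusted p = 0.447, 0.248, 0.454 and 0.0844) and without hb52-KO KNO3 array 1 (adjusted p = 0.0646, 0.145, 0.102 and 0.0828). The acid call also ended without wild-type KCl array 1, hb52-KO KCl array 1 or hb52-KO KNO3 array 3, the starch call without wild-type KCl array 1 or with normexp, and the guard cell call without wild-type KCl array 1 or 3, wild-type KNO3 array 1 or hb52-KO KNO3 array 3. The slide block gave adjusted p = 0.0507 for the starch list and 0.0665 for the guard cell list. The 20 other lists, photosystems (median -0.01, camera adjusted p = 0.802) among them, were not called.

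The genotype differences under the 2 salts, which share no array, correlated across genes at r = 0.604. All 8 genes called under KNO3 were called under KCl with the same sign, where independent lists would share 1.44, and 74.7% of all genes had the same sign. Within slides 1 to 3 the correlation was 0.341, 0.302 and 0.665.

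The interaction compared the nitrate response of hb52-KO with that of wild type. The largest test statistics were those of the auxin-response genes IAA1 (2.95 ± 0.35, 7.71-fold) and IAA2 (1.76 ± 0.22, 3.37-fold), both with adjusted p = 0.0516 and the same sign on 3 of 3 slides. IAA1 stood at -0.89 ± 0.18 (SD, n = 3) and -1.20 ± 0.56 in wild type with KCl and KNO3, and at -3.31 ± 0.21 and -0.68 ± 0.14 in hb52-KO. limma called 0 genes, with 3383 at an unadjusted p under 0.05, and HB52 (0.47 ± 0.39, adjusted p = 0.499), VAR2 (0.00 ± 0.25), VAR1 (0.47 ± 0.20), AT1G27050 (0.42 ± 0.33), FTSH1 (-0.02 ± 0.28) and FTSH8 (-0.22 ± 0.23) did not pass. The count was 4536 without array 2 of wild type with KCl, IAA1 (adjusted p = 0.0227), IAA2 (adjusted p = 0.0109), VAR1 (adjusted p = 0.0307) and AT1G27050 (adjusted p = 0.0262) among them, 1 without array 2 of wild type with KNO3, 16 without array 3 of hb52-KO with KCl, 4 with a trended robust variance, 6 with the slide as a random block and 11 with array weights.

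As lists, 7 of 30 differed in their nitrate response between genotypes by camera, 6 with a higher response in hb52-KO. With an estimated correlation the adjusted p was 0.723 for each of the 7. Photosystem and Calvin cycle genes differed by a median of 1.06 (25 of 31 higher adjusted over the list alone, camera adjusted p = 3.09e-17), with LHCB5 at 1.31 ± 0.31, and by 1.39, 1.41 and 0.43 on slides 1 to 3. Auxin genes differed by 1.102 (5 of 21, 2.51e-06), chlorophyll synthesis by 1.00 (1 of 12, 0.000195), cell division by 1.78 (0 of 8, 0.00697), anthocyanin genes by 1.15 (0 of 18, 0.0178) and guard cell markers by 1.123 (1 of 5, 0.0403), each with its count adjusted over the list alone and its camera adjusted p. Examples are GUN5 at 1.14 ± 0.29, PIN7 at 1.66 ± 0.40 and TT8 at 1.13 ± 0.58, with adjusted p = 0.307 for GUN5 and 0.332 for TT8. Phosphate starvation genes differed by -0.63 (0 of 19 adjusted over the list alone, camera adjusted p = 0.00386), with PAP10 at -0.62 ± 0.24. On slides 1 to 3 the anthocyanin median was 3.096, -0.22 and 0.27, the cell division median 4.09, 0.91 and 0.43 and the phosphate median -1.64, -0.55 and -0.0037, and the other lists kept their sign on all 3. With the slide as a block the guard cell list had an adjusted p of 0.0756. The anthocyanin and guard cell calls both ended with normexp (adjusted p = 0.0784 and 0.143), without wild-type KCl array 1 (adjusted p = 0.0525 each), without wild-type KCl array 2 (adjusted p = 0.104 and 0.0833) and without wild-type KNO3 array 3 (adjusted p = 0.134 and 0.0934). The anthocyanin call also ended without hb52-KO KCl array 1, the guard cell call without wild-type KNO3 array 2 or hb52-KO KCl array 3, the phosphate call without wild-type KNO3 array 2 (adjusted p = 0.0538), and the cell division call with array 2 of both KCl groups left out, a setting chosen after seeing the data. The senescence, hypoxia and heat shock lists (camera adjusted p = 0.151 each) and the 20 others were not called.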

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

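The checks of the HB52 spot, of the 23 nitrate-inducible genes and of array 2 of wild type with KCl were chosen after these results were seen. So were those of the slide position, of the shift of the hb52-KO KCl arrays and of the genes that differed between genotypes in both salts.

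The HB52 spot stood out in data outside the main measurement: on 9 arrays its deposited median pixel signal was far from the mean pixel signal of the same spot. The tolerance was 1.1 pixel standard deviations. Of 542640 spots over all arrays 10 passed it, 9 of them HB52 and 1 a bright-corner control, and the largest other difference was 0.6919. The 9 arrays were those whose deposited numbers were rounded to 3 digits. A median cannot lie farther from the mean of the same pixels than their standard deviation. On these arrays the deposited median of the spot therefore cannot belong with its deposited mean and standard deviation. Which of these values is wrong, and why, was not tested.

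By the test of the difference itself, 7 lists differed in their nitrate response between genotypes, with camera adjusted p = 3.09e-17 for photosystems and Calvin cycle, 2.51e-06 for auxin transport and response, 0.000195 for chlorophyll synthesis, 0.00386 for phosphate starvation, 0.00697 for cell division, 0.0178 for anthocyanin and flavonoid synthesis and 0.0403 for guard cell and stomatal lineage markers. With an estimated correlation the adjusted p was 0.723 for each of the 7, fry called 0 lists, and the guard cell list had adjusted p = 0.0756 with the slide as a block and 0.0833 without array 2 of wild type with KCl.

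Of 23 nitrate-inducible genes 4 were called lower on the KNO3-labelled arrays in wild type and 16 in hb52-KO, where 1 was called higher. The hypothesis that the salt labels were exchanged in both genotypes predicted lower values for most of them, and by sign alone 19 of 23 were lower in both genotypes, on genes chosen after their values were seen, so the hypothesis stays open. A longer-term response to nitrate in seedlings kept on ammonium was not tested. Array 2 of wild type with KCl alone did not account for it, since the group means behind the 16 calls in hb52-KO do not use it and BT1, BT2, NIA2 and CIPK3, 4 of the 23, were called lower in wild type without it; that 21 of 21 genes lower in wild type kept their sign without it decides little, as the genes were chosen and 12 of them moved towards 0. All arrays of each of the 4 groups lay at one slide position, so position cannot be told from group.

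The hb52-KO KCl arrays and array 2 of wild type with KCl were shifted together. Array 2 did not carry the genotype difference, because for 8 of 8 genes called under KNO3 it lay nearer to wild type. Noise of dim probes did not account for the shift either, as 62.3% of the genes in the top quartile of signal were called for nitrate in hb52-KO, against 52.2% of all genes. A state of a culture or sample not tied to genotype stays open: the deviation of array 2 from its group correlated with the difference of hb52-KO KCl from hb52-KO KNO3 at r = 0.769 over 21289 genes, but array 2 had been singled out for lying with the hb52-KO KCl arrays, so this value restates that and decides nothing.

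The 8 genes that differed between genotypes in both salts were SR30, QQS, VAR2, MAF5, AT1G05540, MRD1, HEI10 and AT5G03090. By a cutoff in annotated genes, set for this check, 0 of the 8 lay close to HB52. A chromosome segment linked to HB52 did not account for SR30, QQS, VAR2, AT1G05540, MRD1 and HEI10, which lay on other chromosomes. MAF5 and AT5G03090 lay on its chromosome, 1398 and 6390 annotated genes away. For them a linked segment stays open, because a distance in genes does not show where such a segment ends. MRD1 and HEI10 lay 2 genes apart on chromosome 1. Whether loss of HB52 or other differences between the lines underlie these 8 cannot be told with 1 line.

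Other splits of the arrays, 3 against 3, were too few for a share under 0.05. As many genes as in the real grouping were called in 1 of 10 splits for nitrate in wild type (9 genes, highest other 0), 1 for nitrate in hb52-KO (11145, highest other 1), 1 between genotypes under KCl (7711, highest other 501) and 2 under KNO3 (8, highest other 33). For the interaction the real count was 0, so every one of the 100 drawn splits had to give as many and the comparison decides nothing. Genes were called in 7 of the other splits, all of which kept the hb52-KO groups whole (1, 2, 7891, 8214, 9838 and 10381 genes, and 11554 as the highest other); 3 more that kept them whole gave 0, as did all 89 that mixed them. Counts so far above the real one point to a structure of the samples: these splits set the nitrate difference of hb52-KO, with its 11145 calls, against a relabelled wild-type one, so they do not show what chance gives.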

How the results depend on the processing

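No named gene or list that was called took a call of the opposite sign in an alternative, and neither correlation between contrasts changed sign. The signs of the other called genes were not compared between settings. Median scaling turned the majority of calls. The share of higher calls went from 53.5% to 33.7% for nitrate in hb52-KO and from 44.7% to 65.2% between genotypes under KCl. Counts stayed within 1.5 times the reported value in 19 of 29 alternatives for nitrate in wild type, 27 for nitrate in hb52-KO, 19 between genotypes under KCl, 28 under KNO3 and 22 for the interaction; the cause was not tested for the rest. Nitrate in wild type (9 genes) gave 5 with no filter on dim probes, 5 with the replicate block, 5 with slide as a fixed block, 0 with only the groups compared, and 2 to 14 leaving out 1 array. Nitrate in hb52-KO (11145) gave 7268 with normexp and 5169 with a fold of at least 2. Between genotypes under KCl (7711) the count was 2561 with normexp, 8 with only the groups compared, 4243 with the deposited value table, 3214 with a fold of at least 2, 12098 with array 2 of both KCl groups left out, an alternative added after seeing the data, and 950 to 12150 leaving out 1 array. Under KNO3 (8) array weights gave 10531; that estimate stopped before convergence, with weights of 0.17 to 16.3. The interaction (0) gave 6 with slide as a random block, 4 with trend and robust, 11 with array weights, 4275 without both arrays 2, and 0 to 4536 leaving out 1 array. The genotype difference of HB52 with the deposited table was -3.481 under KCl (adjusted p = 0.0096). Under KNO3 it was -3.339 and uncalled (adjusted p = 0.0674), where the reported log2 difference was 0.01. Its uncalled nitrate differences turned from -0.64 to 1.08 in wild type and from -0.17 to 1.22 in hb52-KO.

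With an estimated correlation camera called 0 lists in every contrast. The reported calls were 8 lists for nitrate in wild type (1 with fry, 4 to 8 leaving out 1 array), 6 for nitrate in hb52-KO (15 with fry, 11 with normexp, 5 to 10 leaving out 1 array), 8 under KCl, 10 under KNO3 (2 with fry, 6 to 16 leaving out 1 array) and 7 for the interaction (0 with fry). The list that fry called in wild type was nitrate reduction and siroheme (fry adjusted p = 0.00196). In hb52-KO its fry adjusted p was 0.00141. Agreement of the nitrate responses, 0.751, was 0.4988 without both arrays 2 and 0.4946 to 0.8009 leaving out 1 array.

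The replicate block gave 5, 11129, 7178, 7 and 0 genes in the order of the contrasts above. Replicate numbers did not pair the arrays throughout: of 18 pairs 8 had r over 0.1, from -0.4949 to 0.5699, and 8 were best with their own number. Between the salts, the hb52-KO arrays were all best with their own number (r = 0.098, 0.242 and 0.067 for arrays 1 to 3). So were arrays 2 and 3 of wild type (r = 0.430 and 0.570), but not array 1 (r = 0.093). Between genotypes only array 1 was, and not for every pair of groups. Between 69.9% and 82.45% of spots were well above background, which limits what dim genes can show.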

Other observations

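The glutamine, glutamate and asparagine list was not called as a list in hb52-KO, and 52.2% of all genes were called for nitrate there. Of its 13 genes 2 rose and 6 fell on the KNO3-labelled arrays (camera adjusted p = 0.473), the chloroplast genes GLN2 (0.73 ± 0.17) and GLU1 (1.91 ± 0.32) rising and GLN1;4 (-1.08 ± 0.34) and GDH2 (-1.40 ± 0.21) falling. Under KCl the list had 4 genes higher and 3 lower in hb52-KO than in wild type (camera adjusted p = 0.55), with GLU1 at -1.59 ± 0.32, GLN1;4 at 1.55 ± 0.34 and ASN2 at -2.33 ± 0.42. Of 5 ammonium transport genes 1 rose with nitrate in hb52-KO, AMT1;2 (1.84 ± 0.22), and 1 fell, AMT1;1 (-0.54 ± 0.20), and the list was not called (camera adjusted p = 0.912). Both measured CC-type glutaredoxins passed in hb52-KO with nitrate, GRXS13 at -1.43 ± 0.23 and GRX480 at 2.38 ± 0.85.

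Of 15 class I homeodomain-leucine zipper genes, the family of HB52, 8 rose and 4 fell with nitrate in hb52-KO (camera adjusted p = 0.366), with HB40 at 1.97 ± 0.24 and HB-12 at -0.96 ± 0.25. Under KCl 2 were higher and 7 lower in hb52-KO than in wild type (camera adjusted p = 0.41), with HB40 at -1.42 ± 0.24 while HB-12 was higher (adjusted p = 0.0163).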
